A study of Homo sapiens with 6 samples.

How the data were processed

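The series holds RNA-seq libraries of cells labelled A549, 3 in a control group and 3 in a FOXD3 knockdown group, taken from the genotype each label gives. RNA was extracted with a column kit and libraries were made with the TruSeq RNA kit, per the labels' protocols. TopHat2 2.0.12, Bowtie, Cufflinks 2.0.2, Cuffdiff and the human build hg19 are named in the submitters' processing notes, with no role or order; read length, strand setting and gene annotation are not given in the sources used here. The authors deposited FPKM values in a table per library, per the file headers, with a symbol, Entrez number, locus and gene ontology terms for each gene. These tables list no gene at 0, so a symbol that a table does not list was set to 0 FPKM; of 70 symbols above 5 FPKM in 1 library and not listed in another, 60 were small RNAs, so a missing value can be a failed estimate. The authors also deposited a table of their comparison with an FPKM value per group, a log2 fold change, a p-value and a false discovery rate, per the file headers, and its subset of called genes; that table gives 1 value per group and was not used for any test here. Recomputing from its FPKM columns showed that its log2 fold change is knockdown over control. Its smallest p-value, 5e-05, is shared by 850 genes.

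A symbol at several loci (331 of 17789 symbols, mainly alternative haplotypes and copies) was summed over its loci. Genes with near-identical paralogs or pseudogenes share reads, so how the authors' software divided them can change the values, and without a stated strand setting overlapping genes cannot be separated. The 10 most abundant symbols held 8.6% to 9.69% of each library's FPKM total. Small nucleolar RNAs held 4.83% of it in knockdown replicate 2 and 0.975% to 1.92% in the other libraries. The files hold no counts, so no count model was used. To estimate depth, the FPKM of a single fragment was read from 97 intronless genes of at least 2500 bp (length within 10% of GENCODE 29, GRCh38, which was used only for gene properties and never for coordinates), taking values that imply 5000000 to 12000000 fragments; 4 to 9 genes per library fell in that window. The length limit and window were set after values had been seen. With so few genes, and a window that the estimate cannot leave, the estimate is rough. Coordinates are those of the authors' tables on hg19, written 1-based.

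Genes with a mean of at least 0.5 FPKM over the 6 libraries were kept, and log2(FPKM + 1) was tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend, two-sided, Benjamini-Hochberg adjusted p under 0.05), with no covariate because the labels give no batch or pairing. FOXD3 was tested with the exact two-sided permutation test of the difference in means. Lists of 44 gene groups fixed before the data were examined were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists that had at least 5 tested members, and beside it with an estimated correlation and with fry. Camera was run with its mean-variance trend, a setting chosen after a first run without it had been seen. Gene ontology terms with 15 to 300 tested genes were tested by camera in the same way. Beside each list stand the members past the threshold over all genes tested and those adjusted over the list alone.

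The rule for named genes was fixed beforehand: FOXD3; the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold, with a mean of at least 5 FPKM in the higher group, a value in all 6 libraries, groups that do not overlap and an ordinary gene symbol; up to 4 called members with the largest absolute change of each list that passed or held at least 5 called members; and markers of other cell types at 5 FPKM or more. Genes given besides these were named after their values were seen; they are CDKN2A, CDKN2B's neighbour MTAP, VIM, PTPRC, CD14, TNF, NFKBIA, RELB, TNFAIP3, S100A7, LEMD1, CCL20, NNMT, CDH5, ESAM, COL1A1, ESR1 and B2M. Not every gene the rule selects is printed, and some genes are not reported here.

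On libraries simulated from the real means and spreads, for the comparison of knockdown with control over 13340 genes, limma recovered 16%, 68%, 100% and 100% of genes changed by 0.25, 0.5, 1 and 2 on the log2 scale, and 4.1% of calls were false. Only 50 genes were changed at each size, drawn from those with a mean log2(FPKM + 1) above 1. In the real comparison 63.5% of genes passed, which loosens the adjusted threshold. The simulated shares therefore do not give the recovery of small changes in the real data. A simulation with no change gave 0 calls. In simulated data with 1 shifted list camera called it and 0 others; the simulated genes vary independently, so this does not test the preset correlation. Alternatives covered the pseudocount (0.1 and 0.5), the filter (none, and 5 FPKM), median scaling, quantile normalization, eBayes without a trend or with robust estimation, each library left out, a fold-change limit, and for lists an estimated correlation and fry. Added after seeing the data were a run without symbols at several loci, removal of each library's trend on transcript length and GC content, and camera without its mean-variance trend. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.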

Results

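RNA sequencing was carried out on 6 libraries from cells labelled A549, a human non-small-cell lung cancer line. The labels put 3 libraries in a control group described as wild type and 3 in a FOXD3 knockdown group. FOXD3 is a forkhead transcription factor best known from the neural crest and from pluripotent cells. It was targeted with a pool of small interfering RNAs delivered by a lipid reagent, and the knockdown was examined 72 h after transfection, per the labels' protocols, which do not say what the control wells received. Each library came as FPKM values, which are fragments scaled to transcript length and to the mapped total, without read counts, so the depth is known only by estimate. The value of a single fragment in intronless genes put it at 6580000 to 7910000 fragments per library. Only values implying 5000000 to 12000000 fragments were read, so the estimate had to fall in that window. Single genes ran from 5440000 to 10020000, and a depth outside the window cannot be excluded. Control libraries listed 16229 to 16288 gene symbols above 0, and knockdown libraries 15651 to 15754. Values below are the mean FPKM ± SD over n = 3 libraries, and log2 changes are knockdown minus control on the log2(FPKM + 1) scale, which understates the change of low genes. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

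The first question was whether the targeted gene was lower in the knockdown libraries. FOXD3 (Entrez 27022, a single exon of 2068 bp on chromosome 1, 63788730 to 63790797, hg19) stood at 0.152, 0.291 and 0.134 FPKM in control replicates 1, 2 and 3. It was not listed in knockdown replicates 1 and 3 and stood at 0.0749 FPKM in knockdown replicate 2. Every control value was above every knockdown value, and the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. At the estimated depth these values correspond to about 2.09, 3.96 and 1.99 fragments in the control libraries and 1.09 in the knockdown library that listed the gene. A greater true depth would raise these numbers in proportion. On this estimate FOXD3 transcript was close to the detection limit in both groups. The gene lay under the filter for the comparison of all genes, and the size of its reduction was not measurable at this depth.

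**Figure D1:**
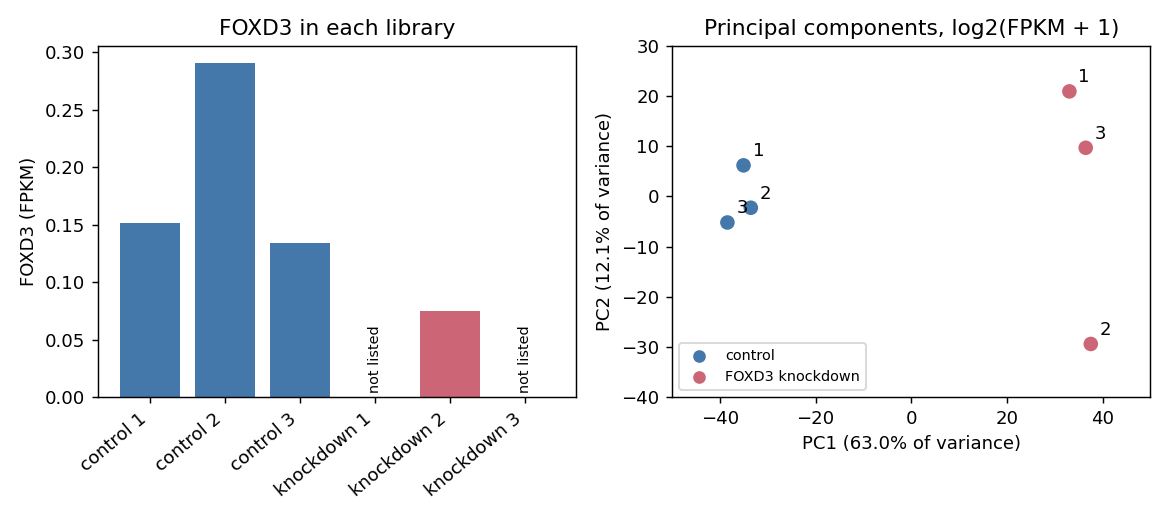
The left panel shows FOXD3 in FPKM in each of the 6 libraries, as bars from 0, with controls in blue and knockdown in red; the highest value, 0.291, is in control replicate 2, and the gene is not listed in 2 knockdown libraries. The right panel places each library, numbered by replicate, on the first and second principal components of log2(FPKM + 1), which hold 63% and 12.1% of the variance; the groups lie apart on the first, and knockdown replicate 2 lies apart from replicates 1 and 3 on the second.

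The second question was which genes differed between knockdown and control cells. Inflammatory and acute-phase genes were among those that fell furthest. SAA1, an acute-phase serum amyloid A protein (chromosome 11, 18287808 to 18291523, hg19), went from 747 ± 143 FPKM in control to 3.91 ± 0.712 in knockdown libraries, a log2 change of -7.24 (SE 0.15; limma, Benjamini-Hochberg adjusted p = 5.1e-08). SAA2, its close paralog, went from 178 ± 32.6 to 0.548 ± 0.156, and reads of the pair may be split uncertainly between them. IL8, a neutrophil chemokine, was 33.9-fold lower and IL6, an inflammatory cytokine, 24.9-fold lower by mean FPKM. LCN2, a secreted iron-siderophore binding protein, was among the most abundant of these transcripts and went from 2645 ± 380 to 313 ± 18.1. The other genes with the largest falls under the rule fixed beforehand were PDZK1IP1, C15orf48, S100A8, CXCL1, CFB, IL32 and HLA-B, with log2 changes between -4.85 and -3.02; CFB and HLA-B were summed over several haplotype loci. The largest rises were smaller than the largest falls. TFF1, a secreted trefoil peptide of mucous epithelia (chromosome 21, 43782391 to 43786644, hg19), went from 2.10 ± 0.372 to 44.3 ± 5.38 FPKM, a log2 change of 3.87 (SE 0.115; limma, Benjamini-Hochberg adjusted p = 3.6e-07). KRT4, an epithelial keratin, was 6.9-fold higher, SPP1 (osteopontin) 4.72-fold, DIO2, a deiodinase that activates thyroid hormone, 4.14-fold, and GAL, the neuropeptide galanin, 4.09-fold. GPX2, a glutathione peroxidase, went from 112 ± 7.99 to 418 ± 6.56. SPANXA2, SPANXB2, ATAD3B, ALPP, SNRNP25 and C9orf140 completed this group, with log2 changes between 1.71 and 2.68; SPANXA2, SPANXB2, ATAD3B and ALPP have near-identical copies or close paralogs, so their values are uncertain.

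**Figure D2:**
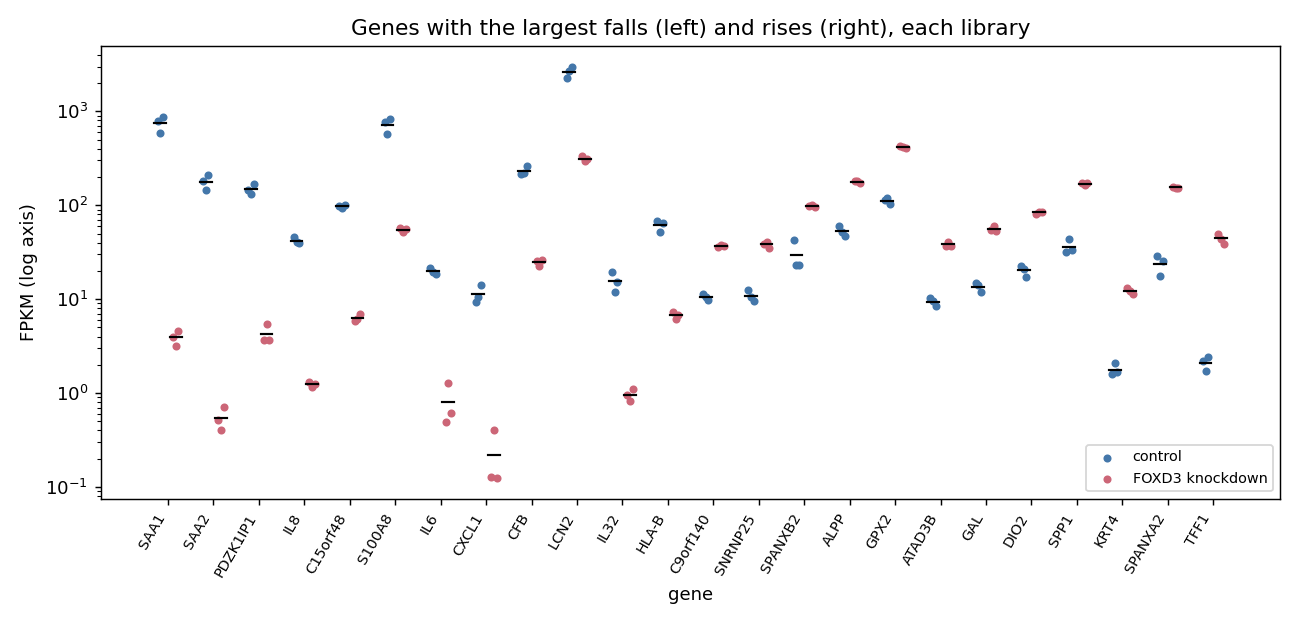
FPKM on a log axis of the 12 genes with the largest falls and the 12 with the largest rises, in order of log2 change; each point is a library (blue, control; red, FOXD3 knockdown) and each black line a group mean. The groups do not overlap for any gene drawn, and SAA2 spans the widest gap between group means on this axis, from 178 in control to 0.548 FPKM in knockdown.

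Of 13340 genes tested, 8467 (63.5%) passed limma's test at the adjusted threshold of 0.05, 3417 higher and 5050 lower in the knockdown libraries. Of these, 228 were at least 2-fold higher and 765 at least 2-fold lower on the log2(FPKM + 1) scale, while 4261 (50.3%) changed by under 0.5. The 2-fold counts depended on the setting: 362 higher and 599 lower after median scaling, 332 and 527 after quantile normalization, and 383 and 1440 with a pseudocount of 0.1. The 2 groups of libraries did not overlap in 9224 genes (69.1%), where chance gives 10%. The direction of the many small changes depended on scaling. With FPKM as deposited 40.4% of calls were higher. The share was 52.1% (4415 higher, 4059 lower) after median scaling and 52.4% (4304 higher, 3909 lower) after quantile normalization. Without rescaling, a filter at 5 FPKM gave 47.4% (2967 higher, 3295 lower), so the balance also depended on low genes. The median log2 change of all tested genes was -0.087 as deposited and 0.025 after quantile normalization, so small changes of gene groups are read relative to that shift. Pearson correlations across genes were 0.9738 to 0.9825 between libraries of a group and 0.932 to 0.9435 between groups, and no pair of libraries shared more than 2 identical values among the 15000 or more symbols listed in both.

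Gene lists fixed before the data were examined were then compared with all other tested genes. Of 37 lists with at least 5 tested members, 22 passed the camera test with its preset correlation, 9 higher and 13 lower. With an estimated correlation 0 lists passed camera after adjustment, 7 had an unadjusted p under 0.05, and the smallest adjusted p was 0.0525; fry, which asks only whether a list moves on balance, called 31.

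The NF-kB and inflammatory list fell as a whole, with 30 of 30 members lower (30 adjusted over the list alone) and a median log2 change of -1.85. For the NF-kB list camera gave a Benjamini-Hochberg adjusted p = 1.54e-13 and adjusted p = 0.0525 with an estimated correlation. Beside the genes named above it held TNF, the cytokine itself, and NFKBIA, RELB and TNFAIP3, components and inhibitors of the NF-kB pathway. Interferon-response genes were lower in 40 of 41 (40 adjusted over the list alone), with a median of -0.83. For interferon-response genes camera gave a Benjamini-Hochberg adjusted p = 1.59e-09 and adjusted p = 0.2 with an estimated correlation. IFITM1, an antiviral membrane protein, went from 23.9 ± 5.52 to 6.85 ± 1.16 FPKM, OASL from 86.2 ± 6.58 to 33.7 ± 2.87, and STAT2, a transcription factor of interferon signalling, from 15.2 ± 0.593 to 5.86 ± 0.309. PSMB9, an immunoproteasome subunit summed over several haplotype loci, was 2.65-fold lower. Of the 12 leukocyte markers, 3 passed the filter and all 3 (3 adjusted over the list alone) fell with these lists: LCP1, an actin-bundling protein also found in carcinoma cells, from 95.2 ± 6.89 to 25.5 ± 1.85, CD68 from 74.0 ± 4.75 to 66.0 ± 0.82, and CD14 from 2.92 ± 0.613 to 1.25 ± 0.304. The CD68 call was lost in several settings. Among them were median scaling (limma adjusted p = 0.527) and the runs without control replicate 3 (0.0569) or knockdown replicate 1 (0.0851), 2 (0.0597) or 3 (0.073). Its adjusted p ranged from 0.00479 to 0.539 over 16 settings. The pan-leukocyte gene PTPRC stood at 0.227 ± 0.071 and 0.194 ± 0.043.

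The 2 cell-cycle lists and the DNA repair list were mostly higher. In the G2/M and mitosis list 36 of 37 members were higher (36 adjusted over the list alone), with a median log2 change of 0.86. For the G2/M list camera gave a Benjamini-Hochberg adjusted p = 2.83e-18 and adjusted p = 0.0525 with an estimated correlation. KIF20A, a mitotic kinesin, went from 20.4 ± 0.428 to 58.5 ± 1.68 FPKM, CDC20, an activator of the anaphase-promoting complex, from 54.5 ± 7.43 to 150 ± 8.45, and the kinetochore motor CENPE from 2.50 ± 0.534 to 8.53 ± 0.748. Of 40 G1/S and replication genes 36 were higher and 1 lower (37 and 2 adjusted over the list alone), with a median of 0.81. For the G1/S list camera gave a Benjamini-Hochberg adjusted p = 5.06e-14 and adjusted p = 0.2 with an estimated correlation. CCNE2, cyclin E2, went from 7.56 ± 0.432 to 22.1 ± 0.35, and the replication licensing factor CDC6 from 12.8 ± 0.341 to 29.7 ± 0.67. DNA repair genes were higher in 17 and lower in 3 of 26 (17 and 3 adjusted over the list alone), with EXO1, XRCC2 and MSH6 each 1.54- to 1.86-fold higher. For DNA repair genes camera gave a Benjamini-Hochberg adjusted p = 0.000609 and adjusted p = 0.0952 with an estimated correlation.

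Lists of ribosome biogenesis, the proteasome and heat shock were mostly higher as well. Ribosome biogenesis factors were higher in 26 of 28 (26 adjusted over the list alone), with a median log2 change of 0.80. For ribosome biogenesis factors camera gave a Benjamini-Hochberg adjusted p = 1.54e-13 and adjusted p = 0.087 with an estimated correlation. NOP16 went from 21.2 ± 1.10 to 63.0 ± 1.02 FPKM and NOP2, an rRNA methyltransferase, from 18.5 ± 1.38 to 46.8 ± 0.944. Proteasome subunits were higher in 29 of 31 (30 adjusted over the list alone), median 0.49, with PSMA3 going from 145 ± 8.88 to 266 ± 8.79. For proteasome subunits camera gave a Benjamini-Hochberg adjusted p = 7.28e-12 and adjusted p = 0.22 with an estimated correlation. Heat shock genes were higher in 14 of 16 (14 adjusted over the list alone), median 0.55, and HSP90AA1, the inducible HSP90 chaperone, went from 807 ± 7.47 to 1974 ± 30. For heat shock genes camera gave a Benjamini-Hochberg adjusted p = 2.22e-08 and adjusted p = 0.0952 with an estimated correlation. Chaperones of the unfolded protein response were mixed, with 14 higher and 6 lower of 22 (14 and 6 adjusted over the list alone): HSP90B1, the endoplasmic reticulum HSP90, was 2.14-fold and CRELD2 2.2-fold higher, while ERO1LB was 5.35-fold and DNAJB9 2.23-fold lower. For the chaperone list camera gave a Benjamini-Hochberg adjusted p = 0.00438, which became 0.0521 after quantile normalization (range over 12 camera settings 0.00209 to 0.0521), and adjusted p = 0.546 with an estimated correlation. Cytosolic ribosomal proteins went the other way, with 53 of 62 lower and 4 higher (54 and 4 adjusted over the list alone) and a median of -0.25, which came to -0.14 after median scaling (34 lower) or quantile normalization (35 lower); RPS9 went from 2017 ± 43.7 to 1287 ± 35.5. For cytosolic ribosomal proteins camera gave a Benjamini-Hochberg adjusted p = 7.08e-07 and adjusted p = 0.439 with an estimated correlation.

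**Figure D3:**
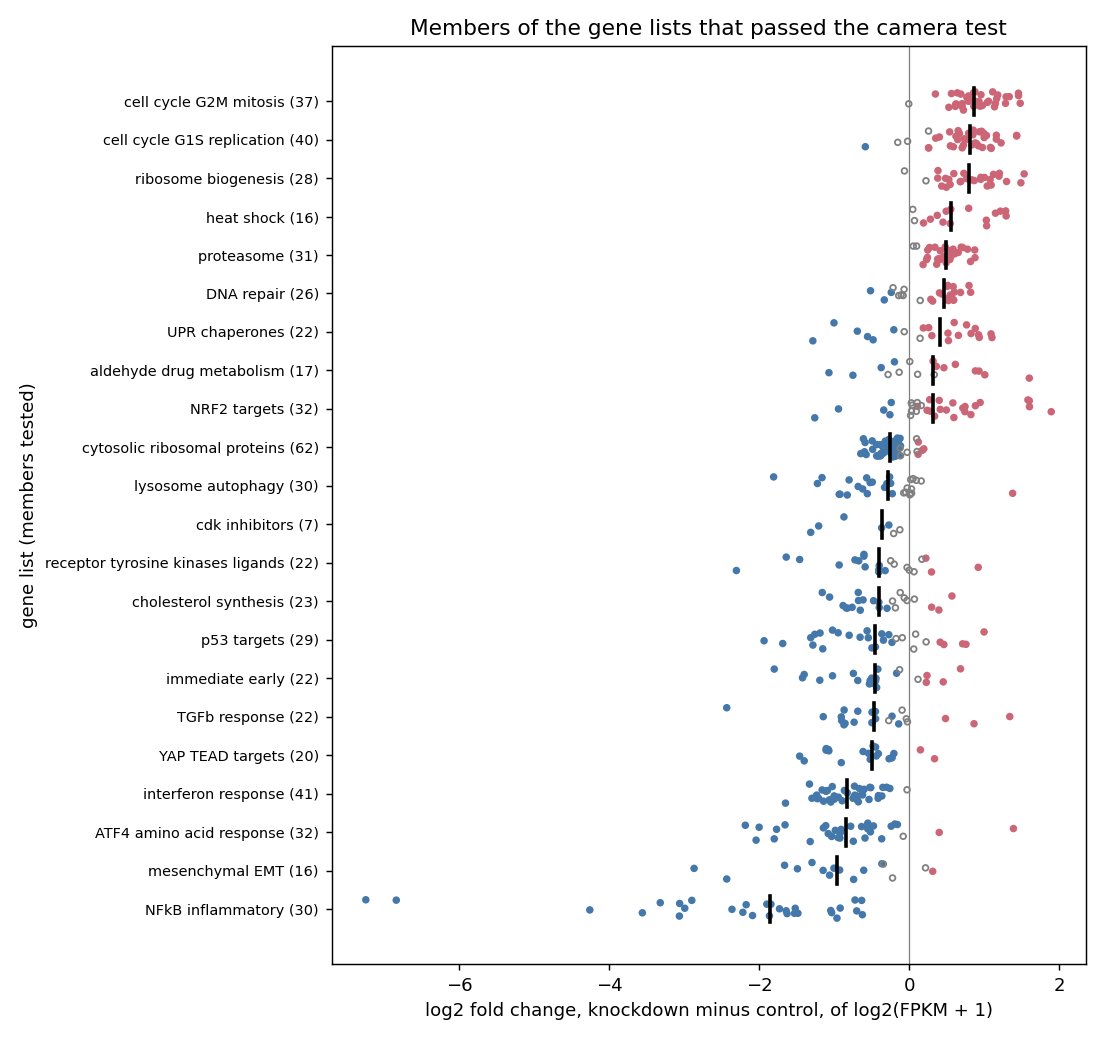
Log2 change (knockdown minus control) of every tested member of the 22 lists that passed camera with its preset correlation, ordered by list median (black line), with the number of members in brackets. Filled points passed limma's adjusted threshold, red higher and blue lower, and open points did not; the NF-kB list has the lowest median, -1.85, and the G2/M list the highest, 0.86, while under median scaling and quantile normalization the ribosomal protein median moves from -0.25 to -0.14.

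Targets of ATF4 and p53 and the CDK inhibitors were mostly lower, while more targets of NRF2 were higher than lower. Targets of ATF4, the transcription factor of amino acid shortage, were lower in 29 and higher in 2 of 32 (29 and 2 adjusted over the list alone), with a median log2 change of -0.85. For ATF4 targets camera gave a Benjamini-Hochberg adjusted p = 2.22e-08 and adjusted p = 0.201 with an estimated correlation. ASNS, asparagine synthetase, went from 147 ± 9.53 to 35.9 ± 3.07 FPKM, CTH, cystathionine gamma-lyase, from 13.4 ± 1.14 to 2.19 ± 0.695, and CHAC1, which degrades glutathione, from 21.2 ± 0.737 to 4.38 ± 0.242. Targets of p53 were lower in 19 and higher in 5 of 29 (19 and 5 adjusted over the list alone); GDF15, a stress-induced cytokine, was 4.07-fold lower, BBC3, the pro-apoptotic protein PUMA, 3.67-fold, and CDKN1A, the CDK inhibitor p21, 2.6-fold. For p53 targets camera gave a Benjamini-Hochberg adjusted p = 0.0358 and adjusted p = 0.2 with an estimated correlation. A gene ontology term for p53-mediated cell cycle arrest after DNA damage had 41 higher and 10 lower of 63. Proteasome genes were not counted apart in it, so it cannot be set against the p53 targets. For that term camera gave a Benjamini-Hochberg adjusted p = 1.57e-05 and adjusted p = 0.432 with an estimated correlation. CDK inhibitors were lower in 5 of 7 (6 adjusted over the list alone), among them CDKN1C, from 3.07 ± 0.348 to 0.789 ± 0.405, and CDKN2B, from 16.1 ± 1.10 to 8.41 ± 1.25. For CDK inhibitors camera gave a Benjamini-Hochberg adjusted p = 0.0358, which became 0.0577 with the length and GC trend removed and 0.0509 in camera without its mean-variance trend, both settings added after seeing the data (range over 12 camera settings 0.0161 to 0.0577), and adjusted p = 0.244 with an estimated correlation. CDKN2A, singled out after its values were seen, was abundant in all 6 libraries, at 154 ± 0.814 in control and 128 ± 1.56 in knockdown. Targets of NRF2, the regulator of antioxidant genes, were higher in 20 and lower in 5 of 32 (20 and 5 adjusted over the list alone), with UGDH, ALDH1A1 and OSGIN1 3.06-, 3.09- and 3.53-fold higher beside GPX2. For NRF2 targets camera gave a Benjamini-Hochberg adjusted p = 3.45e-05 and adjusted p = 0.2 with an estimated correlation. The list of aldehyde and drug metabolism was higher in 8 and lower in 4 of 17 (8 and 4 adjusted over the list alone), with EPHX1, microsomal epoxide hydrolase, going from 78.0 ± 2.97 to 158 ± 1.24. For aldehyde and drug metabolism camera gave a Benjamini-Hochberg adjusted p = 0.042, which became 0.0547 after median scaling, 0.0905 after quantile normalization, 0.0777 with a filter at 5 FPKM and 0.0869 without control replicate 1 (range over 12 camera settings 0.0296 to 0.0905), and adjusted p = 0.389 with an estimated correlation.

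The mesenchymal, YAP and TEAD, TGF-beta, immediate-early and receptor kinase lists held more lower than higher members. In the mesenchymal list 12 of 16 were lower and 1 higher (12 and 1 adjusted over the list alone), with a median log2 change of -0.97. For the mesenchymal list camera gave a Benjamini-Hochberg adjusted p = 0.00137 and adjusted p = 0.274 with an estimated correlation. COL6A2, a collagen VI chain, went from 16.4 ± 2.32 to 1.38 ± 0.284 FPKM. Vimentin (VIM), also singled out after its values were seen, stood at 3.79 ± 0.401 and 1.17 ± 0.263. Targets of YAP and TEAD were lower in 18 and higher in 2 of 20 (18 and 2 adjusted over the list alone), with the receptor kinase AXL 2.88-fold and the matricellular protein CYR61 2.69-fold lower. For YAP and TEAD targets camera gave a Benjamini-Hochberg adjusted p = 0.000264 and adjusted p = 0.0952 with an estimated correlation. TGF-beta response genes were lower in 15 and higher in 3 of 22 (15 and 3 adjusted over the list alone); CTGF was 2.01-fold lower, whereas ID3, an inhibitor of helix-loop-helix factors, was 2.61-fold higher. For the TGF-beta list camera gave a Benjamini-Hochberg adjusted p = 0.00733 and adjusted p = 0.163 with an estimated correlation. Immediate-early genes were lower in 16 and higher in 4 of 22 (16 and 4 adjusted over the list alone), with ATF3 4.36-fold, DUSP1 3.02-fold and EGR1 2.64-fold lower. For immediate-early genes camera gave a Benjamini-Hochberg adjusted p = 0.0209 and adjusted p = 0.326 with an estimated correlation. Receptor tyrosine kinases and their ligands were lower in 13 and higher in 3 of 22 (13 and 3 adjusted over the list alone), with HBEGF 6.32-fold lower, VEGFA 1.96-fold lower and AREG, summed over its copies, 3.48-fold lower. For receptor kinases and ligands camera gave a Benjamini-Hochberg adjusted p = 0.0429, which became 0.0576 after quantile normalization, 0.051 with a filter at 5 FPKM, 0.0589 without knockdown replicate 1 and 0.056 in camera without its mean-variance trend (range over 12 camera settings 0.0351 to 0.0589), and adjusted p = 0.2 with an estimated correlation.

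Lysosome and autophagy genes were lower in 18 and higher in 1 of 30 (18 and 1 adjusted over the list alone), with GABARAPL1, an autophagosome protein, 2.37-fold and GAA, lysosomal alpha-glucosidase, 2.31-fold lower, and GLA, alpha-galactosidase, 2.68-fold higher. For lysosome and autophagy genes camera gave a Benjamini-Hochberg adjusted p = 0.0156 and adjusted p = 0.2 with an estimated correlation. Cholesterol synthesis genes were lower in 14 and higher in 3 of 23 (14 and 3 adjusted over the list alone), with MSMO1, a sterol methyl oxidase, 2.12-fold lower. For cholesterol synthesis genes camera gave a Benjamini-Hochberg adjusted p = 0.0371, which became 0.0833 without control replicate 1 and 0.0538 in camera without its mean-variance trend (range over 12 camera settings 0.00487 to 0.0833), and adjusted p = 0.665 with an estimated correlation.

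The other 15 lists did not pass camera, with Benjamini-Hochberg adjusted p from 0.107 to 0.916, although single members passed limma's test. Nuclear-encoded respiratory chain genes were split as deposited, with 14 higher and 8 lower of 42 (12 and 8 adjusted over the list alone). The balance moved with scaling: 18 higher and 3 lower after median scaling, 21 and 4 with the length and GC trend removed, and 9 and 15 after quantile normalization. Camera's Benjamini-Hochberg adjusted p = 0.19 for that list, which passed after median scaling (adjusted p = 0.0296), without control replicate 1 (0.0302) and with the length and GC trend removed (0.0436), with a range over 12 camera settings of 0.0296 to 0.468, while its median turned to -0.073 after quantile normalization. Hypoxia and glycolysis genes were also split, with 13 higher and 9 lower of 31 (13 and 10 adjusted over the list alone): LDHA and ENO1 rose 1.99- and 2-fold while ALDOC was 4.97-fold lower. For that list camera gave a Benjamini-Hochberg adjusted p = 0.213, which became 0.0184 without control replicate 1 (range over 12 camera settings 0.0184 to 0.657). In fatty acid synthesis 7 were lower and 3 higher of 14 (8 and 3 adjusted over the list alone), with SCD, stearoyl-CoA desaturase, going from 395 ± 31.8 to 151 ± 22.6 FPKM. Epithelial junction genes were lower in 14 and higher in 7 of 27 (14 and 7 adjusted over the list alone), with the tight-junction protein CLDN1 3.28-fold lower. Among genes that promote apoptosis 10 were lower and 7 higher of 26 (10 and 7 adjusted over the list alone), PMAIP1 (NOXA) being 3.19-fold lower, and among those that inhibit it 6 were lower and 3 higher of 12 (6 and 3 adjusted over the list alone), with BIRC3 4.29-fold lower and BIRC5 (survivin) 2.25-fold higher. Other forkhead genes were lower in 9 and higher in 4 of 19 (9 and 4 adjusted over the list alone): FOXM1, which drives mitotic genes, went from 23.9 ± 1.31 to 47.2 ± 1.04, FOXA1 from 21.6 ± 0.179 to 33.7 ± 0.451, and FOXE1 from 4.63 ± 0.473 to 1.39 ± 0.0343. Surfactant and alveolar genes were higher in 5 and lower in 3 of 10 (5 and 3 adjusted over the list alone), with CEBPA 1.67-fold higher and LAMP3 2.18-fold lower. Of 12 genes of the small RNA silencing machinery 5 were higher and 2 lower (5 and 1 adjusted over the list alone). Notch targets were higher in 3 and lower in 2 of 13 (3 and 2 adjusted over the list alone), and replication histones in 3 and 2 of 12 (2 and 1 adjusted over the list alone). Squamous markers were higher in 3 and lower in 2 of 8 (3 and 2 adjusted over the list alone). Neural crest genes were higher in 1 and lower in 4 of 6 (1 and 4 adjusted over the list alone), with ETS1, a transcription factor, 2.4-fold lower. WNT targets were higher in 5 and lower in 3 of 12 (5 and 3 adjusted over the list alone), and MAPK output genes in 4 and 7 of 17 (4 and 7 adjusted over the list alone). For WNT targets the median was -0.078 and the mean -0.064 while camera ranked the list as higher than other genes.

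A further 7 lists had under 5 tested members and were not tested as lists. Of 10 endothelial markers 2 were above the filter, CDH5 and ESAM, and both were lower (2 adjusted over the list alone). Metallothionein genes gave 1 higher and 1 lower of 4 (1 and 2 adjusted over the list alone), and pluripotency genes 1 higher and 2 lower of 4 (2 and 2 adjusted over the list alone). COL1A1, the fibroblast marker above the filter, stood at 3.91 ± 0.404 and 3.20 ± 0.231 FPKM and passed only adjusted over the list alone. From the list of markers of other lines ESR1 and IGF2BP1 were above the filter and did not pass (0 adjusted over the list alone); IGF2BP1 stood at 14.9 ± 0.218 and 14.8 ± 0.156. Among erythroid markers 0 were above the filter, and the leukocyte markers are described beside the inflammatory genes.

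The gene ontology terms annotated in the authors' files were tested in the same way. Of 1254 terms 210 passed camera, 136 higher and 74 lower; with an estimated correlation 0 passed camera after adjustment and 161 had an unadjusted p under 0.05. mRNA splicing via the spliceosome had 113 genes higher and 10 lower of 165. For the splicing term camera gave a Benjamini-Hochberg adjusted p = 1.44e-15 and adjusted p = 0.167 with an estimated correlation. This group lies outside the fixed lists. The mitochondrial ribosome had 16 higher and 1 lower of 22. For the mitochondrial ribosome camera gave a Benjamini-Hochberg adjusted p = 2.77e-05 and adjusted p = 0.383 with an estimated correlation. The MHC class I protein complex had 15 lower and 0 higher of 19. For the MHC class I term camera gave a Benjamini-Hochberg adjusted p = 0.000107 and adjusted p = 0.279 with an estimated correlation. TAP-dependent presentation of exogenous antigen by class I had 42 higher and 15 lower of 66, but 42 of its genes are proteasome genes by symbol (35 higher, 4 lower), and the other 24 had 7 higher and 11 lower. For the TAP-dependent term camera gave a Benjamini-Hochberg adjusted p = 0.000692 and adjusted p = 0.518 with an estimated correlation. The inflammatory response had 94 lower and 21 higher of 151. For the inflammatory response camera gave a Benjamini-Hochberg adjusted p = 0.000434 and adjusted p = 0.226 with an estimated correlation.

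The authors' deposited table of their own comparison covered 12275 genes and called 1059, 395 higher and 664 lower, all with a false discovery rate under 0.01 and an absolute log2 fold change of at least 1. Among 11581 genes measured in both, all 1029 genes called in the authors' deposited table passed limma's test here in the same direction, where 7627 of the shared genes passed without a fold limit. With at least a 2-fold change required here too, 914 passed and 725 of these were called in the authors' deposited table. Log2 fold changes in the authors' deposited table correlated across genes with those computed here at Pearson r = 0.941 (genes are not independent replicates), and were higher by a median of 0.104. For SAA1 the authors' deposited table gave a log2 fold change of -7.45 and for TFF1 4.52. Some genes named above were not called there, among them CXCL1 (authors' false discovery rate 0.0214), GLA (0.522), RPS9 (0.103) and CD68 (0.945). FOXD3 itself had no row in the authors' deposited table.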

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

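Removal of the length and GC trend, omission of symbols at several loci and camera without its mean-variance trend were chosen after seeing the data. Over the alternatives, the number of called genes ran from 7536 to 8469 when each library was left out in turn. The 2-fold limit gave 993 genes, 228 higher and 765 lower, a balance that scaling and the pseudocount move, as given beside those counts. A filter at 5 FPKM, which tests fewer genes, gave 2967 higher and 3295 lower. The higher and lower shares turned with scaling, as given beside the main counts, and were 50.7% higher with the length and GC trend removed. In 2569 refits of 162 named genes, 2526 kept their direction and side of the threshold, and 40 lost the call: these are refits of CDKN2C, HEYL, HIST2H4A, KRT6A, SNAI2, SOX9 and CD68. IGF2BP1, not called in any setting (adjusted p 0.14 to 0.976), changed sign to 0.05455 after quantile normalization, 0.09711 after median scaling and 0.04831 with the length and GC trend removed; the cause was not tested. FOXD3 was lower in the knockdown group under median scaling (exact p = 0.1), quantile normalization (exact p = 0.2) and without each library. With an estimated correlation camera called 0 gene lists and 0 terms (7 and 161 at an unadjusted p under 0.05), as that setting widens the error; camera without its mean-variance trend called 19 lists and 203 terms. In 517 refits of 37 lists, 461 were the same; apart from the estimated correlation, 13 lost the call, in 5 lists (chaperones of the unfolded protein response, CDK inhibitors, cholesterol synthesis, aldehyde metabolism, receptor kinases), and 13 gained one. Direction turned, in lists not called, for forkhead genes (median 0.042 at 5 FPKM, 0.03 after quantile normalization, and -0.168 to -0.069 over the runs without a library, turning without control replicate 2 or knockdown replicate 2), respiratory chain genes (-0.073 after quantile normalization), replication histones (0.027 at 5 FPKM) and, by fry, hypoxia genes (0.184) and WNT targets (-0.078); the cause was not tested. Of genes the authors called, 673 were shared at 5 FPKM or more, where fewer genes are compared. Count models were not run because the files hold no counts, and a row status column to filter on was not found in these files. No paired analysis was possible because the labels carry no replicate numbers. Depth limits FOXD3 itself, at 3.96 fragments or fewer per library by a rough estimate that its window confines.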

Other observations

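S100A7, LEMD1 and CCL20 were not listed in any of the 3 knockdown libraries while every control library held them above 1 FPKM, a selection made after the values were seen. S100A7, an antimicrobial calcium-binding protein of epithelia, stood between 12.1 and 19.5 FPKM in the 3 control libraries. LEMD1 stood at 9.26 ± 3.32 (SD, n = 3) there and the chemokine CCL20 at 2.69 ± 0.77. TNF was summed over several haplotype loci and went from 7.81 ± 1.40 to 0.101 ± 0.112, and NNMT, nicotinamide N-methyltransferase, from 5.53 ± 1.52 to 0.0326 ± 0.0565. B2M, the light chain of class I molecules, went from 703 ± 51.2 to 347 ± 12.2. Squamous keratins moved in both directions, with KRT6B at 27.7 ± 5.94 and 12.2 ± 0.897, KRT17 at 45.2 ± 5.51 and 27.8 ± 1.60, and KRT5 at 0.542 ± 0.139 and 2.54 ± 0.0122.

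Chosen after the results they bear on had been seen were the test of cells that keep this stretch of chromosome 9 (CDKN2A was known, MTAP was not), the leukocyte test and the upper-quartile test of the ribosomal protein list; the other tests were written before their values were seen, although the main list medians were known. CDKN2A was abundant in all 6 libraries, whereas A549 is commonly described as carrying a homozygous deletion of CDKN2A and its neighbour MTAP, as background knowledge that these files cannot check. Reads of a copy elsewhere counted for CDKN2A would leave MTAP near 0, and MTAP was at least 9.2 FPKM in every library, which argues against that explanation. The same value, 9.2 for MTAP with CDKN2A at 125.8 or more, is what cells that keep this region would show, so another line, or another line mixed in, may be a candidate explanation for both groups alike. Vimentin at 3.79 ± 0.401 FPKM in control, where A549 is usually described as rich in it, goes the same way, but no genotype was analysed here and the labels stay as given.

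The fall of the NF-kB list and the rise of the G2/M list were weighed next. Under median scaling and quantile normalization the medians nearest 0 were -1.76 and 0.89. Median scaling uses 1 factor per library, from 0.959 to 1.058, and moves all genes the same way. It took the NF-kB median from -1.85 to -1.76 and the G2/M median from 0.86 to 0.97. Factors so near 1 could not have brought both lists to 0, so median scaling was no test of that cause. With the trend on length and GC removed the list medians were -1.76 and 0.85, which argues against that bias as the whole cause. Leukocytes mixed into the control libraries would bring all their abundant transcripts, and the median leukocyte marker stood at 0.2 FPKM in control, although LCP1 and CD68 are high. Causes that stay open include a response to FOXD3 knockdown and a response to transfection that the control wells may not share. A difference in culture state such as density also stays open. These and other causes were not tested, because the design has a single siRNA pool and the labels describe neither the control treatment nor a batch.

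The fall of the ribosomal protein list, with a median of -0.25, was smaller. Its median nearest 0 was -0.14 under median scaling or quantile normalization and -0.15 with the length and GC trend removed, between the bounds set beforehand, so those tests left both biases undecided. At the preset correlation the list still passed camera under both scalings (highest Benjamini-Hochberg adjusted p = 0.000349, also the highest of 12 settings that began at 1.65e-08) and with the trend removed (2.26e-05), but with an estimated correlation it did not pass even as deposited (0.439). The upper quartile of its members stayed under 0, at -0.01 under quantile normalization and -0.05 with the trend removed. That test would have favoured a bias as the whole cause only if the median reached 0. The medians were already known when it was chosen, so it decides nothing. The bounds were set on the list median itself and not relative to all genes. They therefore do not say how much scaling or length and GC bias added. A response to knockdown or to transfection stays open and untested.

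The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05, and the real split alone (1 of 10) gave the highest count each time. It called 8467 genes against at most 1 in another split, 22 gene lists against at most 19, and 210 terms against at most 110. Each other split mixes the groups 2 to 1 and keeps part of the real difference, so its calls do not measure false calls. Yet some lists that failed camera in the real split passed in others. Hypoxia genes did so in 3 of 9 (smallest adjusted p = 9.34e-06 against 0.213) and respiratory chain genes in 3 (9.34e-06 against 0.19). Squamous markers did so in 2 (0.000588 against 0.405). The kept part of the difference may not account for every such call. Among lists that passed, camera's adjusted p was smaller in another split than in the real one for cholesterol synthesis (1.91e-05 against 0.0371) and unfolded-protein chaperones (0.00156 against 0.00438). The same held for CDK inhibitors (0.0149 against 0.0358), immediate-early (0.0124 against 0.0209), mesenchymal (0.00108 against 0.00137) and lysosome genes (0.0149 against 0.0156). The real split does not single these out. The other lists that passed had their smallest value there.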
